A study of Caenorhabditis elegans with 2 samples.

How the data were processed

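The samples were 2 biological replicates of whole *C. elegans* L1 larvae with an NHR-85-GFP fusion, taken by ChIP-seq with an anti-GFP antibody after sonication, per the labels. Both carried the same source label and formed 1 group, so no test between conditions was possible. The labels call them separate biological replicates, so differences between them hold both biological and technical spread.

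The 9 deposited peak lists are narrowPeak tables, per the files' descriptions. Peaks were called for each replicate and on the pooled reads of both, against a control alignment, on ce10 and on ce11, per the files' descriptions. The IDR-thresholded lists were made from the replicate and pooled lists, per the same source. The aligner, the peak caller, its version and its thresholds are not given in the sources used here. The deposited signal value of a peak is in the peak caller's own units, and whether it is normalized to depth is not given in the sources used here. The deposited −log10 q-value of a peak reached its ceiling of 3.51 in 67.8% of the ce11 IDR-thresholded peaks, so it was not used to rank. The p-value column is not filled. The deposited summit position was used for every annotation and motif step. Signals are the authors' and were used only to rank, filter or describe peaks within a list. Every IDR-thresholded ce11 line was found to be 1 of the 2410 strongest lines of the pooled list, with a lowest signal of 97.2. The ce10 pooled list and the ce10 replicate 1 list both stop at 30000 lines. No list gives read counts, so depth and its effect on weak peaks are unknown.

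Lines with the same interval and 2 summits were reduced to the stronger one. A summit that lay 1 bp past the end of its peak was set to the end. Genes and transcript starts came from Ensembl release 115 for WBcel235, which is the ce11 assembly, and sequence from the RefSeq copy of the same assembly. Names of microRNA genes were taken from the RefSeq gene table through their locus tags. No ce10 genome was used, so annotation and motif work was on ce11 only. For the random placement of ce10 peaks, chromosome ends were taken as the furthest peak end in the ce10 lists.

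Overlap meant at least 1 bp. Random placements kept each peak on its chromosome (1000 draws, seed 11). The reciprocal overlap alternative used 100 draws, and its smallest p is 0.0099. A promoter ran from 1000 bp upstream to 200 bp downstream of any transcript start, and a summit in several promoters counted for each gene. Feature classes were assigned in a fixed order that put promoters first. Gene lists were tested by two-sided Fisher's exact tests over 19973 protein-coding genes with Benjamini-Hochberg adjustment over 27 lists. The heterochronic microRNAs were tested over 261 microRNA genes, a departure from the written design, which named protein-coding genes. All members of the lists were found, except that lin-4, a microRNA gene, was not counted in the insulin and starvation list. Motifs were counted on either strand in windows reaching 50 bp to each side of the summit and compared with windows 500 bp to each side by the exact McNemar test, keeping the larger p of the 2 sides, with adjustment over 9 motifs. Odds ratios of gene lists and gene classes were formed after a constant smaller than 1 was added to each count. This raises them where few genes have a peak, so they differ there from ratios of the plain counts. Shares have 95% Wilson intervals, which cover counting error only.

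Genes were named by a rule fixed before the data were examined, as were the gene lists, the tests and the first set of alternatives. It took the 25 strongest IDR-thresholded peaks found in both replicates, each named by the nearest transcript start of any gene type, except within 40 kb of nhr-85 or unc-119. It also took up to 4 members with the strongest promoter peak from every list, all members of the heterochronic and clock lists, and the 2 transgene loci. Where the nearest start was that of a non-coding RNA or piRNA gene, the nearest protein-coding gene was added after the values were seen, except that puf-9 and nhl-2 were members of a list.

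Alternatives covered the overlap rule, stricter and relaxed peak sets, each replicate alone, the promoter window, the tie between peak and gene, operon-like genes, the regions of the transgene, the motif window and flank, and the genome build. Protein-coding starts only, a background without chemoreceptor and F-box genes, a background without piRNA genes and the 2 ce10 IDR-thresholded lists were added after seeing the data.

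Uniqueness of sequence was measured as the share of 31-mers found once in the assembly on both strands. The read length is not given in the sources used here, so this length is a stand-in. For gene families, names with the same letters and at least 10 protein-coding genes were tested, leaving out 14 names that stand for a phenotype or a screen rather than a family.

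The steps were tested on simulated data. For the gene lists, simulated over 19973 genes with a 5-fold higher share in some lists, 98.8% of changed lists of 25 or more genes were recovered, 86.1% of changed lists of any size, and 1.55% of unchanged lists were called. Simulated genes had peaks independently of each other, so peaks shared between genes are not covered. For transcript starts over 2404 peaks, a made share of 44.2% was found as 44.2%, and 4% of random sets were called. For AGGTCA over 2404 windows, a made share of 7.03% was found as 7.12%. Simulated summit and flank windows had the same base composition, unlike the real ones, so calls caused by composition are not covered. For replicate overlap over 2404 peaks, 85.7% was found when 85% of peaks were kept and the rest placed at random. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.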

Results

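Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the nuclear hormone receptor NHR-85 occupied the genome of *Caenorhabditis elegans* larvae. NHR-85 is the nematode homologue of the mammalian clock repressor Rev-Erb and has been studied for its part in the timing of larval development. The worms carried a transgene that expresses NHR-85 with green fluorescent protein (GFP) at its C-terminus, and an antibody against GFP was used to recover the bound DNA. Hermaphrodites were synchronized in the first larval stage (L1), as larvae starved after bleaching, and were collected 6 h after synchronization as whole animals. Whether they were fed in those 6 h is not stated in the label. There was 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates and between the peaks and the genome. Read numbers are not in the peak lists, so the depth of each library is unknown. The peak set used throughout is the deposited ce11 list that passed the irreproducible discovery rate (IDR) threshold, with 2410 lines in 2404 distinct intervals. These peaks had a median width of 430 bp and covered 946058 bp.

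The first comparison asked whether both replicates marked the same sites. The strongest site in each replicate was the same place, an intron of pqn-41 (chromosome III, 1921181 to 1921679), a gene for a glutamine-rich protein that is required for the death of the linker cell. Its peak signal, in the peak caller's units, was 1094 in replicate 1 and 1138 in replicate 2. The next 3 sites also had equal ranks in both replicates. They lay in pqn-41, in an intron of Y111B2A.12 and beside Y48G8AR.8. Of the 2404 strongest peaks of replicate 1, 2036 (84.7%, 95% Wilson interval 83.2 to 86.1) overlapped one of the 2404 strongest peaks of replicate 2. Random placement on the same chromosomes gave 1.92% ± 0.280 (SD over 1000 placements), and the one-sided empirical p was 0.000999, the smallest that this number of placements can give. Sharing was 100% among the strongest 601 peaks of replicate 1 and 56.7% among the last 601 of these 2404, where the cut at 2404 can remove partners. Against all 13289 peaks of replicate 2, 2396 of the 2404 (99.7%) overlapped, with 10.1% at random. Across 5852 overlapping pairs, signal had a Pearson r of 0.837 on the log2 scale. Peaks are not independent replicates, so no p is given for this correlation.

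**Figure D1:**
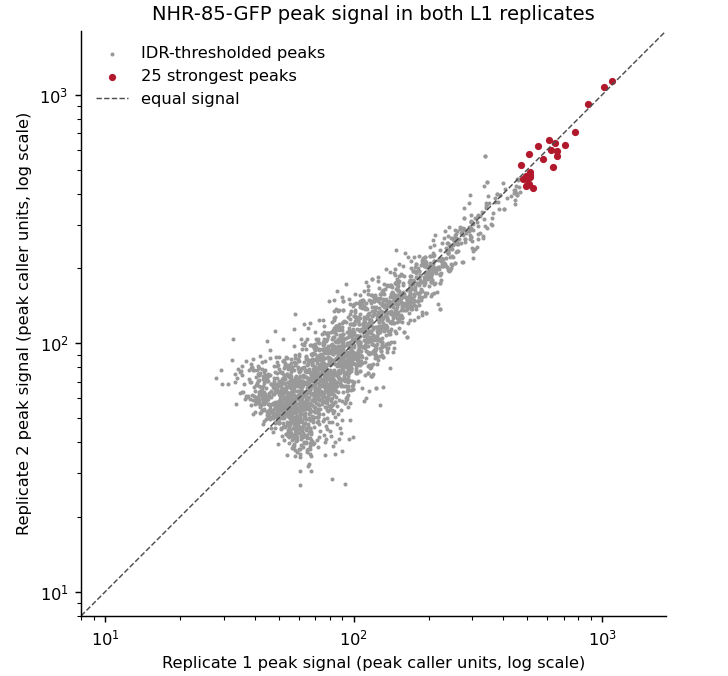
Peak signal of IDR-thresholded peaks in replicate 1 (x axis) and replicate 2 (y axis), both in peak caller units on log scales, with 1 point per peak found in both replicates. The 25 strongest peaks (red) lie near the line of equal signal, and the scatter is widest at low signal.

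The second comparison asked where the strongest sites were and what lay beside them. Among the 25 strongest peaks, with pooled signals from 922 to 2228, 10 were in promoters, 8 in introns and 7 between genes. Chromosome III held 10 of them, and 4 of these were in introns of pqn-41, with pooled signals of 2228, 2095, 1224 and 1144. Promoter sites included 2 genes for proteins of the large ribosomal subunit. The rpl-3 peak (III, 3867423 to 3867740) was centred 277 bp upstream of the start and had signals of 647 and 639 in the replicates. The rpl-35 peak (III, 7854547 to 7854834) was centred 457 bp upstream, with signals of 513 and 465. Others lay 239 bp upstream of dmd-7, 692 bp upstream of Y24D9A.6, 130 bp upstream of tos-1 and 417 bp upstream of ifbp-1.

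A peak 310 bp upstream of puf-9, which encodes a Pumilio-family RNA-binding protein (X, 5841112 to 5841470), had signals of 512 and 477. A peak 838 bp upstream of nhl-2, a cofactor of the microRNA machinery (III, 4899749 to 4900099), had signals of 493 and 473, and it was also 585 bp upstream of tag-340. Both of these summits were nearer to the start of a non-coding RNA gene, W06B11.7 and F26F4.14. The same held for dmd-7 (K08B12.6), sma-9 (T05A10.8), zfp-1 (F54F2.13), nhr-14 (T01B10.13), R03E9.2 (R03E9.6) and F09E10.1 (F09E10.14), and piRNA genes were nearer than C34B4.2 (21ur-11069) and sup-26 (21ur-13313). These 8 genes and tag-340 are named as the nearest protein-coding genes, a choice made after their values were seen. Distal sites lay 2570 bp upstream of the nuclear receptor gene nhr-88 and 1447 bp upstream of nhr-14. Another was 2897 bp upstream of sma-9, a transcription factor of the body size pathway. An intronic site lay near zfp-1, a chromatin regulator. The remaining sites lay near T04C4.3, epg-9 and Y43F8B.2, 1643 bp upstream of C34B4.2, 1990 bp upstream of sup-26, 4467 bp upstream of R03E9.2 and 2174 bp downstream of the F09E10.1 start.

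Over all peaks, promoters held 1649 of 2404 summits, 68.6% (95% Wilson interval 66.7 to 70.4). A promoter is here the stretch from 1000 bp upstream to 200 bp downstream of any annotated transcript start. Random placement gave 38.0% ± 0.962 (SD), so the share was 1.80-fold higher (two-sided permutation p = 0.000999, the smallest possible). The replicates on their own gave 68.7% and 68.5%. Coding exons held 0.416% of summits against 17% at random, and introns 11.9% against 24.5%. Sites in 3′ UTRs and in exons of non-coding transcripts were also below random, at 0.374% against 2.12% and at 0.166% against 1.28% (permutation test, adjusted p = 0.0014 over 7 classes for each of these). Intergenic sequence held 18.4% against 16.7% (permutation test, adjusted p = 0.0303), a call that was lost with the replicate 1 peaks alone (adjusted p = 0.105) and in the stronger 1202 peaks (adjusted p = 0.226). Over the 5852 peaks shared by the replicates, coding exons held 4.46% (0.262 times random, against 0.0244 in the IDR-thresholded set) and 3′ UTRs 1.32% (0.629 times random, against 0.176). The 5′ UTR share, 0.208% against 0.379%, was not past the permutation test (adjusted p = 0.175). Summits lay upstream of the nearest protein-coding start in 76.9% of cases, at a median distance of 662.5 bp in either direction, and 1 random placement gave 43.01% and 1275 bp. Intervals cover counting error only.

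**Figure D2:**
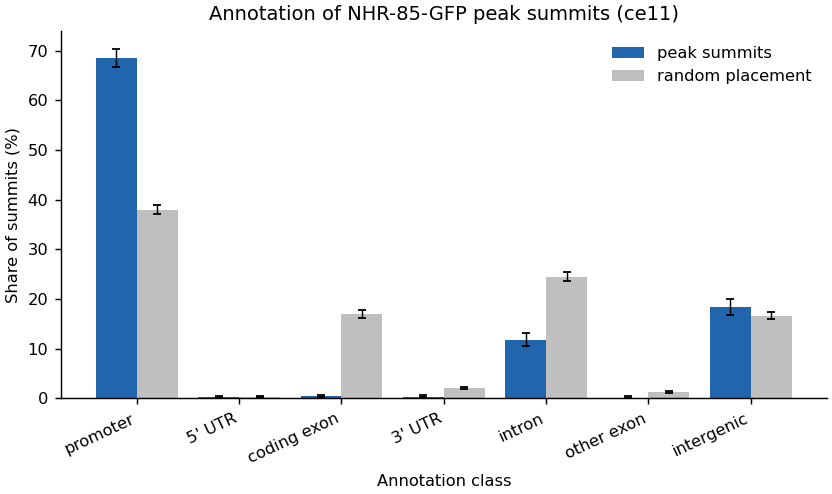
Share of the 2404 peak summits in each annotation class (blue, bars with 95% Wilson intervals) and the mean share over 1000 random placements on the same chromosomes (grey, error bars 1 SD), in percent. Promoters held 68.6% of summits against 38.0% at random, and coding exons 0.416% against 17%.

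Chromosomes differed in peak density. The X chromosome carried 518 peaks, 21.5% of the total (95% Wilson interval 19.95 to 23.2), against 17.7% of the nuclear genome length (exact binomial p = 1.26e-06) and 13.7% of protein-coding genes (exact binomial p = 7.08e-26). Density was 29.2 peaks per Mb on X and ranged on the autosomes from 19.9 on V to 27.2 on III. On the autosomes, 881 of 1886 peaks (46.7%, 44.5 to 49) lay in the central 33.3% of the length (exact binomial p = 3.47e-33). That part of the autosomes holds 38.1% of their protein-coding genes (exact binomial p = 2.81e-14 against this share). Chromosome V was the most centred, with 56.1% of its peaks in that part, and X had 33.4% there. The binomial tests take peaks as independent, but 108 genes had 3 or more peaks nearest to their starts. Their p-values may thus be too small.

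The third comparison asked which groups of genes had NHR-85-GFP peaks at their promoters. There was no untagged strain and no other GFP fusion. Peaks that any GFP precipitation would give can thus not be told apart in any of these groups. Of 19973 protein-coding genes, 1615 (8.09%) had at least 1 IDR-thresholded summit in a promoter. Genes for cytosolic ribosomal proteins were far above this share, with 50 of 81 (61.7%, 95% Wilson interval 50.8 to 71.6). The strongest were rpl-3, rpl-35, rpl-20 and rpl-15, with pooled signals of 1288, 978, 860 and 814. Mitochondrial respiratory chain genes had peaks at 16 of 43 (37.2%, 24.4 to 52.1). They included cox-5A and cox-5B, subunits of cytochrome c oxidase, with signals of 557 and 271. They also included mev-1, a subunit of succinate dehydrogenase, and atp-1 of the ATP synthase, with signals of 355 and 340. Chaperone genes had peaks at 17 of 59 (28.8%, 18.8 to 41.4), led by hsp-90 (656), the mitochondrial chaperonin gene hsp-60 (653), the endoplasmic reticulum chaperone gene hsp-3 (529) and cct-1 (522). By two-sided Fisher's exact tests adjusted over 27 lists, p was 3.14e-33 for the ribosomal, 9.03e-07 for the respiratory chain and 1.40e-05 for the chaperone list. Genes, not replicates, are the units of all the gene list tests, and genes that share a peak are not independent. The replicates on their own gave 61.7% and 63.0% for the ribosomal list and 37.2% and 39.5% for the respiratory chain. When each peak was tied only to its nearest start, the ribosomal share was 39.5% (odds ratio 9.79 against 18.8, Fisher's exact test, adjusted p = 1.08e-16). The chaperone share was then 10.2% (odds ratio 1.77 against 4.72, Fisher's exact test, adjusted p = 0.393).

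The seam and hypodermis, nuclear hormone receptor and lipid metabolism lists were also over-represented. Seam and hypodermis genes had peaks at 8 of 20 (40%, 21.9 to 61.3, adjusted p = 0.00036 by Fisher's exact test). Among them, elt-1, the GATA factor that specifies the epidermis, had a signal of 367. The others named were nhr-25 (272), the cytoskeletal linker gene vab-10 (247) and the seam gene grd-10 (171). Nuclear hormone receptor genes, nhr-85 left out, had peaks at 34 of 273 (12.5%, 9.05 to 16.9, Fisher's exact test, adjusted p = 0.0324), led by nhr-68 (456), nhr-34 (439), nhr-87 (367) and nhr-21 (352). Lipid metabolism genes had peaks at 9 of 41 (21.95%, 12 to 36.7, Fisher's exact test, adjusted p = 0.0128), with the elongase gene elo-1 (178), the fatty acid synthase gene fasn-1 (174), nhr-49 (147) and acs-2 (121) as the strongest. In the stronger 1202 peaks alone, by the same Fisher's exact test, the receptor share was 4.76% (odds ratio 1.14, adjusted p = 0.842) and the lipid share 4.88% (odds ratio 1.39, adjusted p = 0.857), each against 4.34% of other genes. The constant added to each count raised this lipid odds ratio, since only 2 of 41 genes had a peak. The lipid call was also lost with replicate 1 alone (14.6%, Fisher's exact test, adjusted p = 0.252), and the receptor call without chemoreceptor and F-box genes in the background (odds ratio 1.51 against 1.65, adjusted p = 0.0983).

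Histone genes had peaks at 15 of 72 (20.8%, 13.1 to 31.6, Fisher's exact test, adjusted p = 0.00164). A single peak between his-67 and his-68 had a signal of 646 and counted for both, and his-37 (553) and his-42 (182) were the next strongest. This group is uncertain, because its members are near-identical copies. Only 8 of the 72 had a promoter with at least 95% unique 31-mers, and 2 of these 8 had a peak (25%) against 9.003% of other genes with such promoters. The odds ratio of 3.89 was no smaller than the 3.08 of the full list, but 8 genes are too few to test it (Fisher's exact test, p = 0.158). With replicate 2 alone the share was 12.5% (Fisher's exact test, adjusted p = 0.311), with the stronger 1202 peaks 5.56% (odds ratio 1.45, adjusted p = 0.842), and with nearest starts only 13.9% (adjusted p = 0.0605).

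The chemoreceptor, F-box and MATH-BATH, and innate immune effector lists were under-represented. Chemoreceptor genes had peaks at 8 of 1310 (0.611%, 95% Wilson interval 0.310 to 1.2, Fisher's exact test, adjusted p = 1.19e-36), and srh-2, srh-16, srh-76 and srh-17 were the strongest, with signals from 202 to 367. F-box and MATH-BATH genes had peaks at 8 of 395 (2.03%, 1.03 to 3.95, Fisher's exact test, adjusted p = 2.19e-06), among them fbxb-85, fbxa-90, fbxa-83 and fbxb-58. Innate immune effector genes had peaks at 11 of 352 (3.13%, 1.75 to 5.51, Fisher's exact test, adjusted p = 0.000548). The strongest were the antimicrobial peptide genes nlp-24 (327), nlp-31 and nlp-34, which share a peak (300), and fipr-22 (245). C-type lectin genes (clec), a large part of this list, had 1 of 240. Its other families went both ways, with fipr genes at 4 of 29, cnc at 1 of 11, spp at 0 of 31 and lys at 0 of 10. The list without clec genes was not tested. All 3 calls held in each replicate alone. With a promoter of 500 bp the odds ratio was 0.0373 for chemoreceptors, against 0.0692, and 0.131 for F-box and MATH-BATH genes, against 0.245.

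The other 15 lists were not past the test in the IDR-thresholded set. Some of their members had peaks all the same. Insulin and starvation signalling had peaks at 4 of 24 genes (16.7%), akt-2, skn-1, hlh-30 and daf-16, with signals of 228, 227, 210 and 108. This list passed with nearest starts only (20.8%, Fisher's exact test, adjusted p = 0.0446). Molting regulators and cuticle assembly genes had peaks at 5 of 31 (16.1%), including myrf-1 (389), nhr-25, nhr-41 (131) and nhr-23 (131). Vacuolar ATPase genes had peaks at 4 of 20 (20%), which were vha-12, vha-8, vha-15 and vha-1. They passed over the shared peaks (40%, Fisher's exact test, adjusted p = 0.0148) and with a promoter of 2000 bp (30%, adjusted p = 0.0351). Cuticle collagens had peaks at 18 of 174 (10.3%), with col-3 and col-117 sharing a peak of signal 373 ahead of col-10 and col-103. Hedgehog-related genes had peaks at 7 of 85 (8.24%), led by ptr-6, grd-3, grd-10 and grd-13. Wnt and Notch signalling genes had peaks at 3 of 26 (11.5%), which were wrm-1, lit-1 and sys-1. Homeobox genes had peaks at 5 of 86 (5.81%), led by ceh-38, ceh-13, ceh-20 and lin-39. Cytochrome P450 and UGT genes had peaks at 6 of 141 (4.26%), and cyp-13A2 was the strongest with a signal of 575, ahead of cyp-29A4, ugt-13 and ugt-9. Over the shared peaks they had 22 of 141 (odds ratio 1.06 against 0.543).

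Intestinal genes had peaks at 2 of 30 (6.67%), erm-1 and fat-6, with signals of 102.6 and 101.1. The intestinal share was 3.33% with either replicate alone. Pharyngeal genes had 1 of 16 (peb-1), pan-neuronal genes 1 of 25 (snb-1, and 5 of 25 over the 5852 shared peaks), germline genes 2 of 35 (cgh-1 and mes-2) and insulin-like peptide genes 1 of 39 (ins-39). For pan-neuronal genes the share was 8% with either replicate alone, against 4% in the IDR-thresholded set. Body wall muscle genes had 0 of 30, for which the 95% Wilson interval reaches 11.4%. These lists are small, and in the IDR-thresholded set none of them was shown to differ from other genes (adjusted p from 0.270 to 1). Over the shared peaks, insulin-like peptide genes were under-represented (2.56% against 15.1%, Fisher's exact test, adjusted p = 0.0486).

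**Figure D3:**
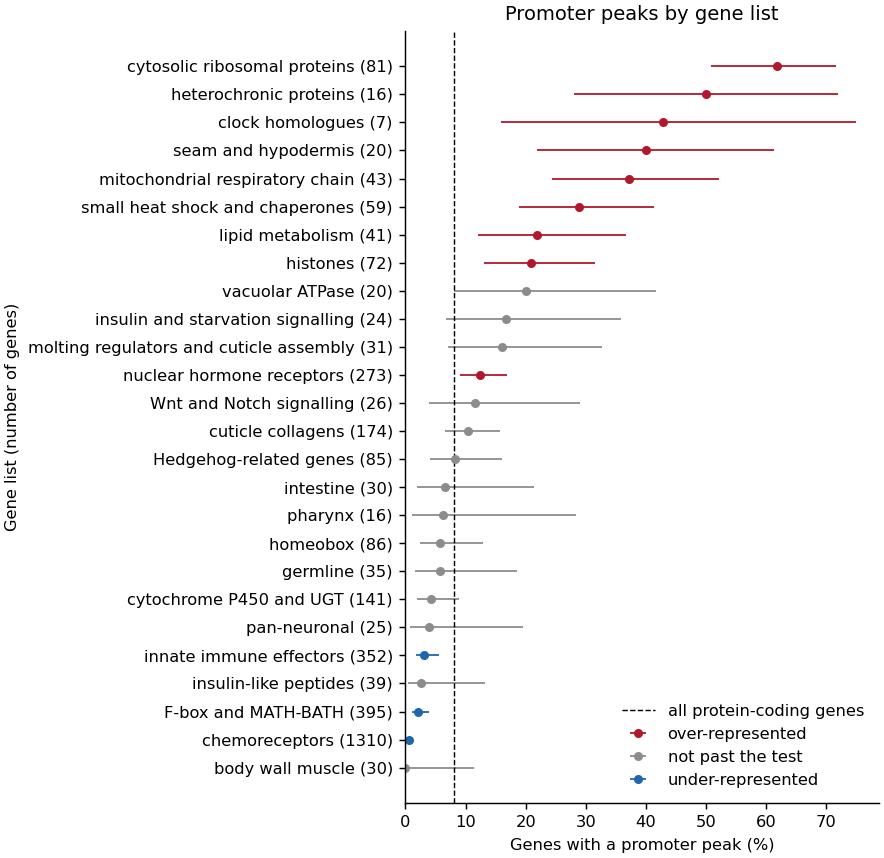
Share of genes with a promoter peak (x axis, percent) in the protein-coding gene lists, with the number of genes in parentheses, points for the share and bars for the 95% Wilson interval. The dashed line marks all protein-coding genes (8.09%). Cytosolic ribosomal proteins were highest (61.7%), and chemoreceptors were at 0.611%.

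The fourth comparison was on the heterochronic pathway, which times larval cell fates and in which NHR-85 has been placed. Promoter peaks were present at 8 of 16 heterochronic protein genes (50%, 95% Wilson interval 28.0 to 72.0, Fisher's exact test, adjusted p = 5.76e-05), and each replicate alone also gave 50%. With a promoter of 500 bp it was 5 of 16 (31.2%, odds ratio 7.17 against 11.4, Fisher's exact test, adjusted p = 0.00793), and over the 5852 shared peaks the odds ratio was 5.66. Besides puf-9 and nhl-2, these were ain-1 (pooled signal 322), a component of the microRNA silencing complex, and lin-28 (301), an RNA-binding protein of early larval fates. The lin-14 promoter (X, 11465165 to 11465594) had a signal of 193, with 105 and 83.5 in the replicates. The remaining genes were the Argonaute gene alg-1 (163), lin-46 (150) and lin-66 (103). The nearest summit was 49 bp upstream of a lin-28 transcript start but within the annotated gene, and 180 bp upstream of lin-14. The alg-1 summit, 381 bp upstream of a start, also lay within its gene. The 8 genes without a promoter peak were lin-29, sea-2, daf-12, lep-2, alg-2, lin-41, lin-42 and hbl-1. For 4 of them a summit lay within 5 kb of a start. It was 1011 bp upstream of hbl-1, just outside the promoter window, 1515 bp upstream of lin-41, 3032 bp upstream of a lin-42 start and 1157 bp downstream of a sea-2 start. Their signals were 129, 288, 187 and 160.

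None of the 6 heterochronic microRNA genes had a promoter peak, for which the Wilson interval reaches 39.0%, against 9.41% of other microRNA genes (Fisher's exact test, p = 1). The nearest IDR-thresholded summit was 1887 bp upstream of let-7, with a signal of 153, which counts as a promoter peak when the promoter reaches 2000 bp. It was 16126 bp upstream of lin-4, 8493 bp downstream of the mir-48 start, 10261 bp downstream of mir-241, 5051 bp downstream of mir-237 and 34111 bp upstream of mir-84. In the unthresholded pooled list the nearest summit to lin-4 was 5328 bp downstream, with a signal of 56.5. Annotated starts of these microRNA genes are mostly those of the hairpins or short transcripts, so promoters of longer primary transcripts can lie outside the window. The let-7 gene is annotated over a longer stretch (X, 14743590 to 14745321), so this limit holds less for it.

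Clock homologues had promoter peaks at 3 of 7 (42.9%, 15.8 to 74.95, Fisher's exact test, adjusted p = 0.0324). They were tim-1, a Timeless homologue (394), the casein kinase gene kin-20 (217) and nhr-23, the ROR homologue (131). The nearest summit was 10 bp upstream of an nhr-23 start. With replicate 2 alone the share was 57.1%. The Period homologue lin-42 and atf-2, ces-2 and aha-1 had none. With the stronger 1202 peaks 2 of the 7 had a peak (28.6%) against 4.33% of other genes, an odds ratio of 10.03 against 8.85 in the full set, and the call was lost (Fisher's exact test, adjusted p = 0.103). It was also lost, by Fisher's exact test, with nearest starts only (28.6%, odds ratio 6.63, adjusted p = 0.145) and with a promoter of 2000 bp (42.9%, odds ratio 6.48, adjusted p = 0.0643). The constant added to each count raises the odds ratios of so short a list.

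The fifth comparison was between classes of genes. Genes for small nucleolar RNAs, which guide the modification of ribosomal RNA, had promoter peaks at 78 of 346 (22.5%), and small nuclear RNA genes of the splicing machinery at 28 of 129 (21.7%). By Fisher's exact test against all other genes, adjusted p was 1.34e-26 and 5.69e-10. Here too genes, not replicates, are the units, and genes that share a peak are not independent. Over the 5852 shared peaks the odds ratio of the small nuclear RNA genes was 2.85, against 4.88 in the IDR-thresholded set. Of the 78 small nucleolar RNA genes, 42 had their peak only in sequence that is also the promoter of a protein-coding gene. Protein-coding genes were above the remaining genes, at 8.09% against 3.55% (odds ratio 2.39, Fisher's exact test, adjusted p = 5.09e-99), and the odds ratio was 1.32 without piRNA genes in the background. Pseudogenes had peaks at 18 of 2128 (0.846%, odds ratio 0.145, Fisher's exact test, adjusted p = 6.03e-31), and the odds ratio was 0.238 over the shared peaks. Transfer RNA genes had them at 41 of 612 (6.70%, Fisher's exact test, adjusted p = 0.180), but were above other genes with replicate 1 alone (8.01%, adjusted p = 0.00789) and with replicate 2 alone (7.35%, adjusted p = 0.0488). MicroRNA genes had peaks at 24 of 261 (9.20%, Fisher's exact test, adjusted p = 0.0154), a call that ended without piRNA genes in the background (adjusted p = 0.331), with replicate 1 alone (7.28%, adjusted p = 0.171), in the stronger 1202 peaks (4.98%, adjusted p = 0.0762) and with a promoter of 500 bp (5.75%, adjusted p = 0.144). The odds ratio was 1.79 in the full set and 1.29, 1.41, 1.78 and 1.56 in these settings, in the same order. Other non-coding RNA genes, at 6.64%, were above all other genes (Fisher's exact test, adjusted p = 1.34e-06), but below them without piRNA genes in the background (odds ratio 0.855, adjusted p = 0.00267). With a promoter of 500 bp they did not pass (4.26%, Fisher's exact test, adjusted p = 0.0773).

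The sixth comparison asked which short sequences lay at the summits. AGGTCA, the core site of many nuclear hormone receptors, was within 50 bp of 157 of 2404 summits, 6.53% (95% Wilson interval 5.61 to 7.59). Windows 500 bp to each side had it in 2.995%, a ratio of 2.18 (exact McNemar test, adjusted p = 2.01e-07). Among the 180 orderings of its letters it had rank 4, and ACGTGA was the highest with a ratio of 3.03. The orderings are not all unrelated controls. ACGTGA overlaps CACGTG, itself enriched at these summits, and AAGGTC (ratio 2.23) overlaps AGGTCA. The rank of AGGTCA was 6 with replicate 2 alone, 8 with replicate 1 alone, 9 within 25 bp of summits, 7 for summits in promoters and 14 for those outside. It was 3 in the stronger 1202 peaks and within 100 bp, and 2 over the 5852 shared peaks and against windows 1000 bp away. The Rev-Erb and ROR response element, a longer version of AGGTCA with an A and T rich 5′ side, was at 13 summits (0.541% against 0.499% in the flanks, exact McNemar test, adjusted p = 1). Of these summits, 12 lay outside promoters (1.59% of 755, ratio 2.18, exact McNemar test, adjusted p = 0.269) and 1 in a promoter (0.0606% of 1649, ratio 0.154, adjusted p = 0.328). Within 25 bp it was at 12 summits, a ratio of 2.4. The exact McNemar p was 0.00195 against the left flank and 0.424 against the right, and the larger gave an adjusted p of 0.745. The element thus passed in no setting, but so few summits leave the test little power. Direct repeats of AGGTCA spaced by 1 or 2 bp were at 0 of 2404 summits, for which the interval reaches 0.160%. The peaks at lin-28, snb-1, akt-2, fasn-1, ifbp-1, nlp-24, grd-3, ceh-20 and cyp-29A4 were among those with AGGTCA.

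GAGAGA and CACGTG were also enriched at summits. GAGAGA was at 25.5% of summits against 5.43% in the flanks, a ratio of 4.70 (exact McNemar test, adjusted p = 6.62e-81). CACGTG, the E-box of basic helix-loop-helix factors, was at 8.44% against 1.77%, a ratio of 4.78 (exact McNemar test, adjusted p = 5.77e-26). Its ratio was 8.10 outside promoters, 3.69 in promoters and 2.76 over the 5852 peaks shared by the replicates. Runs of T were fewer, at 4.58% against 11.4% (exact McNemar test, adjusted p = 3.71e-18). TGATAA, the site of GATA factors, was at 8.49% against 9.26% (exact McNemar test, adjusted p = 0.964), and TTTCTTTC at 2.29% against 1.35% (adjusted p = 0.136). TTTCTTTC passed with windows reaching 100 bp from the summit (ratio 1.80, exact McNemar test, adjusted p = 0.000686) and for summits outside promoters (3.44% against 1.32%, ratio 2.6, adjusted p = 0.0361), but not in promoters (ratio 1.29, adjusted p = 1). Summit windows had 44.3% G+C, against 35.5% and 35.7% in the windows to the left and right.

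**Figure D4:**
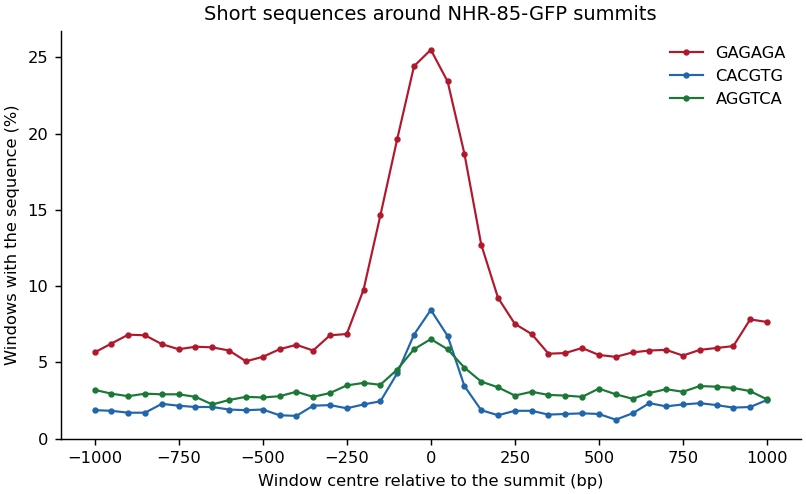
Share of windows reaching 50 bp to each side of their centre (y axis, percent) that hold GAGAGA, CACGTG or AGGTCA on either strand, with windows centred every 50 bp from the summit of 2404 peaks (x axis, bp). Each line peaks at the summit, at 25.5% for GAGAGA, 8.44% for CACGTG and 6.53% for AGGTCA.

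No excess of peaks was found near the transgene's own loci. Read coverage was not examined and peaks were called against a control alignment, so a broad rise in reads there could go unseen. Neither nhr-85 (I, 13055201 to 13062122) nor unc-119 (III, 10902641 to 10908935), the gene used to select transgenic worms, had a promoter peak. Within 40 kb of each gene there was 1 IDR-thresholded peak, against 1.87 and 2.35 at the density of their chromosomes. These were a site 169 bp upstream of athp-1, near unc-119, with a signal of 138, and an intergenic site of signal 100.7 near W05B5.1.

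The lists made on the 2 genome builds differed in length. On ce10 the IDR-thresholded list held 3489 lines, against 2410 on ce11. The replicate 1 list held 30000 lines on ce10 and 8095 on ce11, and the replicate 2 list 25662 and 13297, so the replicate with the longer list differed between builds. The X chromosome held 21.8% of the ce10 peaks and 21.5% of the ce11 peaks. An archived ce10 list held 3400 lines, and 87.6% of the current ce10 intervals overlapped it. Coordinates were not converted between builds.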

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

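The alternatives with the ce10 IDR-thresholded lists, protein-coding starts only, and backgrounds without piRNA genes or without chemoreceptor and F-box genes were chosen after seeing the data. Of the values that answer a comparison, 79 alternatives kept the call or the size and 6 did not. Replicate overlap ranged from 78.2% to 99.7%. The rank correlation of replicate signals went from 0.783 to 0.844 with summits within 100 bp, 0.809 with the strongest 2404 peaks of both, 0.663 with peaks that overlap an IDR-thresholded peak, and 0.612 on ce10. The cause was not tested. The number of over-represented gene lists was 9 and became 5 with the stronger 1202 peaks, where the share of other genes was itself 4.33% or 4.34%. There nuclear hormone receptors (4.76%), histones (5.56%) and lipid metabolism (4.88%) were lost with odds ratios from 1.14 to 1.45, and clock homologues (28.6%) with an odds ratio of 10.03, above the 8.85 of the full set. With nearest starts only, clock homologues (28.6%), histones (13.9%) and chaperones (10.2%) were lost and insulin and starvation signalling (20.8%) was gained. With the promoter of 2000 bp, clock homologues (42.9%) were lost and vacuolar ATPase (30%) was gained. With all peaks shared by the replicates, vacuolar ATPase (40%) was gained above and insulin-like peptides (2.56%) below. Nuclear hormone receptors (12.5%) were lost without chemoreceptor and F-box genes in the background. With 1 replicate left out, histones were at 12.5% to 20.8% and lipid metabolism at 14.6% to 19.5%. The ribosomal, respiratory chain, heterochronic protein and seam lists were called under each alternative. The number of gene classes above all other genes became 3 without piRNA genes in the background. There the other non-coding RNA genes, at 6.64%, turned from above to below the other genes, whose own share went from 5.24% to 7.69%. Of the values for single lists, classes, features and motifs, 360 alternatives kept their call, 18 lost it, 11 gained one and 1 turned. Depth is unknown, so whether weak or missing peaks reflect low depth cannot be judged.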

Other observations

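The family scan, the counts of peaks per gene and the tests of sequence pairs, strength and place were chosen only after the main results had been seen, as were the 3 patterns weighed here. What each test of a pattern would show was written down before it ran, except that the share of AGGTCA in the stronger 1202 peaks had already been seen when its test by peak strength was written. Named gene families were scanned for promoter peaks by the letters of their names. Of 164 families, 6 were over-represented and 7 under-represented by Fisher's exact test with adjustment over all of them. Apart from rpl, rps and his genes, those above were, by Fisher's exact test, sec genes of the secretory pathway (7 of 19, 36.8%, adjusted p = 0.00858), vps genes of endosomal sorting (8 of 31, 25.8%, adjusted p = 0.0359) and dnj genes for J-domain co-chaperones (8 of 29, 27.6%, adjusted p = 0.0246). C-type lectin genes (clec) had 1 of 240. The chemoreceptor families str, srw, srx, srbc and srh had 1 of 193, 0 of 109, 0 of 101, 0 of 71 and 5 of 220, and fbxa genes had 2 of 170.

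Counting each peak for its nearest protein-coding start, 108 genes had 3 or more, and 1501 had 1. The chromatin factor gene egl-27 had 9, with a strongest signal of 412, and mdl-1, which encodes a Mad-like partner of the E-box factor network, had 8, with a strongest signal of 838. The protein kinase gene pkg-2 and the insulin pathway transcription factor gene daf-16 also had 8, with strongest signals of 596 and 317, and mnk-1 had 7 (742). Those with 6 were sma-9, vhp-1, ccch-1, W06H8.6, D2023.1, scd-1 and hlh-30, with strongest signals from 309 to 995. Among microRNA genes, mir-228 had the strongest promoter peak (600), ahead of mir-5549 (407), mir-79 (353) and mir-354 (345), and mir-54, mir-55 and mir-56 shared one (334). Transfer RNA genes sat mainly at weaker peaks. They had promoter peaks at 41 of 612 in the IDR-thresholded set and at 169 of 612 (27.6%) among the 5852 replicate 1 peaks that overlap a replicate 2 peak. In that wider set they were above all other genes (Fisher's exact test, adjusted p = 2.04e-30).

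The 3 enriched sequences were more frequent at summits outside promoters than in them, AGGTCA at 8.61% against 5.58%, GAGAGA at 30.9% against 23.04% and CACGTG at 11.3% against 7.16% (Fisher's exact test, adjusted p = 0.00742, 0.000163 and 0.00172). GAGAGA shared summits less often than independent sites would, both with CACGTG, 36 against 51.8, and with AGGTCA, 27 against 40.03 (Fisher's exact test, adjusted p = 0.0203 for each). CACGTG and AGGTCA shared 12 summits against 13.3 (Fisher's exact test, adjusted p = 0.882).

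A first pattern is that GAGAGA marked the summits more often than AGGTCA, as did CACGTG in the IDR-thresholded set (8.44% against 6.53%) but not over the 5852 shared peaks (5.02% against 5.69%). As a ratio of summits to flanks, CACGTG stayed above AGGTCA over the shared peaks (2.76 against 2.18). Base composition of the summits was argued against as the whole cause for all 3 sequences, because windows matched on G+C content, outside every pooled peak and split by promoter, gave summit ratios of 3.30 for GAGAGA, 2.74 for CACGTG and 1.99 for AGGTCA (exact McNemar p = 5.94e-62, 1.30e-15 and 2.63e-07). A hypothesis is that peak strength may be set by something other than AGGTCA, such as partner factors. AGGTCA was at 4.66% (3.24 to 6.65) of the strongest 601 peaks and 7.49% (5.64 to 9.87) of the weakest 601 (Fisher's exact test, p = 0.0527), which leaves this open, while GAGAGA (29.3% against 22.96%, adjusted p = 0.0226) and CACGTG (11.3% against 5.99%, adjusted p = 0.00412) were more frequent in the strongest. No biological explanation was tested, since there is 1 group and no other factor or untagged strain.

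A second pattern is the near absence of promoter peaks at chemoreceptor genes. Reads shared between paralogs were argued against as the whole cause. Among the 1002 chemoreceptor genes whose promoter has at least 95% unique 31-mers, 7 had a peak, an odds ratio of 0.0713 (Fisher's exact test, p = 2.17e-32). F-box genes gave 7 of 247 and an odds ratio of 0.311 in the same test. These genes may simply be closed in most cells of a whole larva, which was not tested.

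A last pattern is that only 10 of the 25 strongest peaks (40%) were in promoters, against 68.9% of all others (Fisher's exact test, p = 0.00378). It rests on few peaks, since ranks 26 to 50 were at 68%, and 4 of the 25 are in pqn-41, so they are not independent. Reads piled up on sequence repeated in the assembly were argued against, because the median share of unique 31-mers in these 25 intervals was 100% and the lowest was 90.4%. Sequence that has more copies in the strain than in the assembly could still raise signal and stays open, as does a peak that any GFP precipitation would give. No biological explanation was tested.

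Ribosomal protein promoters, the most over-represented group, carried no AGGTCA at 47 summits, for which the 95% Wilson interval reaches 7.56%, against 5.88% of other protein-coding promoter peaks (Fisher's exact test, p = 0.107, adjusted p = 0.357 over 15 tests).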
